A study of Homo sapiens with 20 samples.

How the data were processed

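Gene expression was measured in 20 RNA-seq libraries from a single human induced pluripotent stem cell (iPSC) line and from neurons derived from it by induced transcription factors. Per the labels, the libraries were 3 each of undifferentiated iPSC of lot 1 and lot 2 on day 0, 3 each of spheroid neurons on days 10, 32, 57 and 88 after induction, and 1 each of monolayer neurons on days 66 and 88. The factors that were introduced are not given in the sources used here. Total RNA was purified on small columns and 1 ng per sample was made into cDNA by Smart-seq2, per the labels' protocols. Smart-seq2 primes at poly(A) tails, amplifies full-length cDNA and does not mark the strand, so reads of a gene and of an overlapping antisense transcript cannot be told apart.

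Reads were aligned with HISAT2 2.1.0 and assembled and quantified with StringTie 2.0.6 on GRCh38.p13, per the submitters' processing notes. The annotation release, read length, strand setting and filters are not given in the sources used here. Each deposited table covers 1 library and lists annotated genes, loci that StringTie assembled from the reads, and spike-in references. Per the file headers, the values used were TPM (a share of transcripts), FPKM (fragments scaled by gene length and depth) and coverage. In the deposited TPM column the assembled loci alone sum to 1000000 and the annotated genes list the annotated part of the same reads a second time, so the column was treated as a score that is proportional to TPM within a library. The deposited coverage signal was used only with the deposited FPKM, since their ratio gives the number of aligned bases behind a library. Gene identifiers were matched to GENCODE 29, which held 57763 of the 58011 annotated genes. Counts of reads were not used here, so no count model was fitted.

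The unit of analysis was log2(TPM + 1) of the annotated genes. A fold change on this scale understates the change of genes of low level. Genes with a TPM of at least 1 in at least 3 of the 20 libraries entered the tests, which left 19468 genes, 13601 of them protein-coding. Genes of the Y chromosome and the X-inactivation transcripts were left out of all tests and text. One limma model (version 3.58.1 in R 4.3.3, moderated with an intensity trend and robust settings) was fitted to all 20 libraries with a coefficient per group, and the 7 comparisons were read from it. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05 with a log2 change of at least 1 in either direction. A gene of the monolayer comparison also had to lie outside the range of the spheroid libraries in both monolayer libraries, and the lone monolayer libraries were assumed to vary like the groups of 3. Nothing in the labels says what the biological replicates of a group shared, so p-values measure only the spread between these libraries. The spread of a gene was estimated from all groups of 3 together, iPSC included. A p-value thus does not measure the spread of the compared groups alone.

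Fixed lists of genes, 34 in all, were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over all 217 list tests with at least 4 measured members. A test with an estimated correlation was run beside each. The lists, tests, thresholds, comparisons and most alternatives were chosen before the data were examined. So was the rule for named genes. It took the 5 largest increases and the 5 largest decreases among called protein-coding genes whose libraries did not overlap, up to 4 called members of each list, a preset panel of markers, and the genes of 3 maturation pairs. The maturation pairs were described without a test, and 1 of them and some members of the lists are not reported here.

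Depth was estimated at 2990 to 4096 aligned megabases in the iPSC libraries and 378 to 655 in the neuron libraries, so low genes are measured less precisely in the neurons. The fits were tested on simulated data with 200 of 19468 genes changed. The changed genes were drawn only from those above a TPM of 5 in the reference groups, so the shares found do not cover genes of lower level. Noise was drawn independently for each gene, and the lone monolayer libraries were given the same noise as the groups of 3. In the day 10 against day 0 simulation 36% of genes changed by a log2 of 1, 92% of those changed by 1.5 and 100% of those changed by 2 were called. In the day 88 against day 57 simulation these shares were 38%, 90% and 98%, and in the monolayer simulation they were 42%, 94% and 98%. A change of 1 lies at the call threshold itself. Of the genes changed by 1, 82%, 68% and 62% passed the adjusted p in the 3 simulations. Among unchanged genes 4, 8 and 6 were called in the 3 simulations, and of 100 unchanged lists 0 were called in each by camera. The simulated lists held no correlation between genes, so this does not show how camera treats lists of correlated genes.

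Alternatives were another pseudocount (0.1), no filter and a stricter filter (TPM of at least 5), FPKM in place of TPM, median-of-ratios, quantile and spike-in scaling, removal of mitochondrially encoded genes, a fit of only the compared groups, limma without trend or robust settings, a block for the replicate number, each lot alone as day 0, each monolayer day alone, and leaving out each replicate in turn. After seeing the data, TPM rescaled to a sum of 1000000 per library and the TPM of the assembled loci were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. GC content was not analysed here.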

Results

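Expression was profiled in undifferentiated iPSC and in the neurons made from them over 88 days of culture. Day 0 was represented by 6 libraries from 2 lots of the same cells. Spheroid neurons were sampled on days 10, 32, 57 and 88 with 3 libraries each, and monolayer neurons on days 66 and 88 with 1 library each. Between 13131 and 14786 annotated genes reached a TPM of 1 in an iPSC library and between 14219 and 15455 in a neuron library. The iPSC libraries were deeper, at 2990 to 4096 megabases aligned against 378 to 655 megabases. Mitochondrially encoded genes held 16.8% to 22.6% of the annotated signal in iPSC, 8.18% to 10.37% on day 10, and up to 22.7% in the neurons. Ribosomal DNA loci held 2.75% to 5.22% of the signal in iPSC and 8.08% to 16.1% in neurons. Day 0 also differed from all neuron groups in the naming series of its libraries, which cannot be told apart from the change of cell type, and from the spheroids in its monolayer form of culture.

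Libraries grouped by cell type and then by day. The first principal component held 70.6% of the variance and parted iPSC, at -166 to -152, from neurons, at 39.2 to 85.0, with the monolayer neurons of days 66 and 88 at 65.3 and 72.2 among the spheroids. The second held 8.92% and ordered the spheroids from 76.5 to 78.2 on day 10 through 17.6 to 19.8 on day 32 and -26.2 to -25.1 on day 57 to -43.5 to -38.2 on day 88. Pearson correlations across genes within groups of 3 were 0.956 to 0.974. Those between an iPSC and a neuron library were 0.619 to 0.722.

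**Figure D1:**
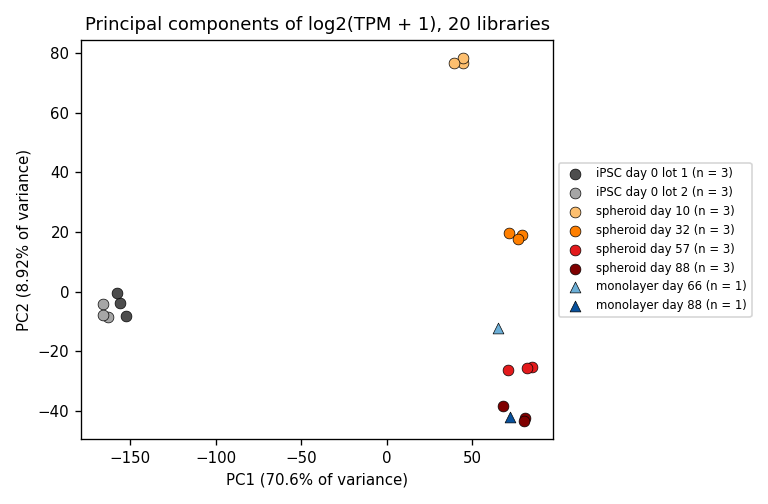
Each point is 1 of the 20 libraries, placed by the first (x axis) and second (y axis) principal component of log2(TPM + 1), with the share of variance on the axes, circles for iPSC and spheroids, and triangles for monolayer neurons. The iPSC lie at the left, from -166 to -152, and the spheroid neurons run from 78.2 on day 10 down to -43.5 on day 88 on the second component.

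The comparison of spheroid day 10 with day 0 asked what the induction changed. By day 10 genes of pluripotency and cell division had fallen and genes of neuronal structure, transmission and fate had risen. POU5F1 (ENSG00000204531.18, chromosome 6, 31164337 to 31180731, GRCh38), the central pluripotency factor, went from a TPM of 167 ± 12.1 in lot 1 and 175 ± 15.0 in lot 2 to 1.32 ± 1.20 on day 10 (SD, n = 3 each), a log2 change of -6.38 ± 0.30 (SE, adjusted p = 2.01e-12). TUBB3, the neuronal beta-tubulin, rose from 20.7 ± 5.01 and 12.4 ± 0.941 to 1174 ± 86.1 TPM (log2 change 6.12 ± 0.11), and SLC17A6, the vesicular glutamate transporter VGLUT2, rose by 7.04 ± 0.19 to 151 ± 19.8 TPM. The largest increase was that of NEUROG3 (ENSG00000122859.4, chromosome 10, 69571698 to 69573238, minus strand), a proneural transcription factor, which went from 0.192 ± 0.137 and 0.260 ± 0.35 TPM to 4210 ± 120 (log2 change 11.77 ± 0.14, adjusted p = 1.77e-20). In the neurons the locus assembled at NEUROG3 covered its coding sequence alone, without the annotated untranslated regions.

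Next to NEUROG3 the largest increases were those of INA (9.29), an intermediate filament protein of neurons, STMN2 (9.16), a regulator of microtubules in growing axons, RTN1 (8.28) and REEP1 (8.07). The largest decreases were those of IFITM1 (-8.81), IFITM2 (-8.08) and IFITM3 (-7.77), membrane proteins that restrict virus entry and are similar in sequence, the NODAL co-receptor TDGF1 (-8.56) and the keratin KRT18 (-8.35). In all, 4438 genes were higher and 3878 lower.

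Of the pluripotency list 21 of 22 tested genes fell and 0 rose (median log2 change -4.17, camera adjusted p = 2.7e-12), among them TDGF1, L1TD1 (-6.50) and NANOG (-3.79). Of the cell cycle list 27 of 28 fell and 0 rose (median -3.83, adjusted p = 1.15e-13), with CDC20, an activator of the anaphase-promoting complex, at -6.44, AURKB, a mitotic kinase, at -5.79, and TOP2A at -4.32. Neurogenic transcription factors rose in 15 of 16 cases (median 4.53, adjusted p = 3.58e-10), including EBF2 (6.73), NEUROD1 (6.53) and NHLH2 (6.49). Of the pan-neuronal list 22 of 24 rose and 1 fell (median 5.02, adjusted p = 4.19e-14), with the neurofilaments NEFM (7.98) and NEFL (7.93) in front. Presynaptic genes rose in 26 of 28 cases (median 2.21, adjusted p = 1.78e-11), among them the vesicle proteins SYT4 (6.81), RAB3A (5.55) and SYP (5.19). Voltage-gated potassium channel genes rose in 14 of 20 cases (median 2.11, adjusted p = 2.79e-05), led by the channel-interacting protein KCNIP4 (5.80). Counts adjusted over the list alone were the same for these 6 lists.

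Genes of the sensory list and of the cholinergic and motor neuron list rose beside glutamatergic genes. The lists do not tell whether these genes mark separate neurons. In the sensory and peripheral list 9 of 14 rose and 0 fell (median 2.61, adjusted p = 4.06e-04), including the filament PRPH (7.41), the transcription factor DRGX (6.68) and the neuropeptide precursor TAC1 (5.94). In the cholinergic and motor neuron list 5 of 7 rose (median 3.75, adjusted p = 7.96e-04), with the homeobox genes ISL2 (6.96) and ISL1 (6.11) and the acetylcholine esterase ACHE (6.03). Glutamate transport and receptor genes rose in 11 of 22 cases (adjusted p = 0.00335), a call lost with an estimated correlation (adjusted p = 0.146 with an estimated correlation). Postsynaptic genes rose in 10 of 20 cases (adjusted p = 0.00493, and adjusted p = 0.179 with an estimated correlation). The subunits GRIN1 (0.43 ± 0.20) and GRIN2B (-0.19 ± 0.18) of the NMDA receptor did not pass. The GABAergic list was not called (1 higher and 2 lower of 7 tested, or 1 and 1 adjusted over the list alone, adjusted p = 0.879), although SST, the somatostatin precursor, rose by 7.96. The GABA-synthesising enzymes GAD1 and GAD2 stayed at group means of at most 0.550 and 0.226 TPM, and the astrocyte filament GFAP at 0.295 TPM or less.

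Cytosolic ribosomal protein genes and mitochondrially encoded genes had lower medians on day 10, next to the lower mitochondrial share of those libraries. Nuclear-encoded oxidative phosphorylation genes had a median of -0.35, which turned to 0.17 under spike-in scaling. That turn rests on the high spike-in level of iPSC lot 2. Of the cytosolic ribosomal protein genes 20 of 40 fell (median -0.97, adjusted p = 6.08e-10, and adjusted p = 0.282 with an estimated correlation). Of the mitochondrially encoded genes 8 of 13 fell (median -1.52, adjusted p = 2.17e-04, and adjusted p = 0.399 with an estimated correlation). Hypoxia and glycolysis genes fell in 10 of 19 cases and rose in 4 (adjusted p = 0.00799, and adjusted p = 0.317 with an estimated correlation), with ADM (-6.14), a vasodilator peptide, and HK2 (-3.57), a hexokinase, among those that fell.

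Spike-in scaling moved the split of this comparison from 4438 higher and 3878 lower genes to 5114 and 2704, and the median of all genes by 0.25. Mean spike-in TPM was 450 in lot 1, 2622 in lot 2 and 745 on day 10. This scaling thus raised day 10 against lot 2 but lowered it against lot 1, so the upward move rests on lot 2. Lower genes were in the majority under median-of-ratios scaling (3916 higher and 4376 lower), quantile normalization (3909 and 4227) and FPKM (3299 and 3473), each of which moved that median by -0.14. With assembled-locus TPM they were also in the majority (4954 higher and 5069 lower), while that median hardly moved. It moved by 0.18 when TPM was rescaled to a sum of 1000000 per library.

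**Figure D2:**
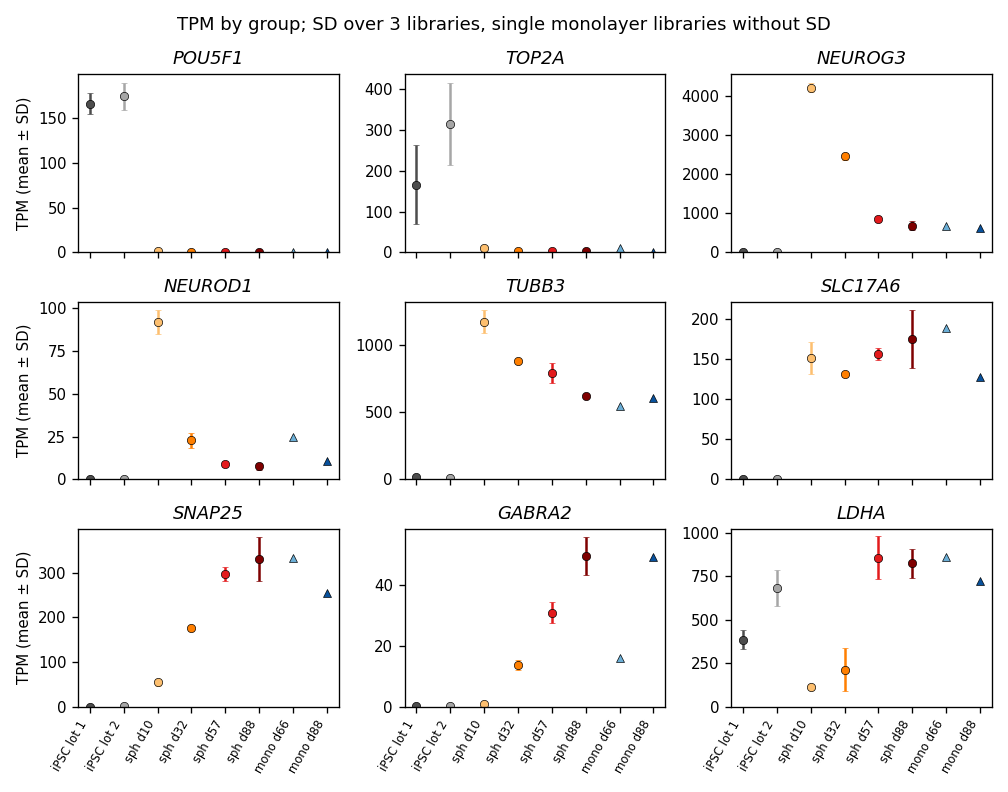
TPM (y axis, linear, from 0, own scale per panel) of 9 genes in the 8 groups (x axis), as mean ± SD over 3 libraries for iPSC and spheroids (circles) and as the value of the single library for monolayers (triangles). POU5F1 falls from 167 and 175 TPM to 1.32 on day 10, NEUROG3 peaks at 4210 on day 10, and LDHA rises from 212 on day 32 to 857 on day 57.

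From day 10 to day 32 presynaptic, GABA-A receptor and voltage-gated sodium channel genes rose as lists while neurogenic transcription factors fell. PHF24 (ENSG00000122733.12, chromosome 9, 34957608 to 34982544) was listed at 0 in all 3 libraries of day 10 and reached 24.8 ± 4.25 TPM on day 32 (SD, n = 3, adjusted p = 3.62e-11). CBLN2, a secreted organiser of synapses, rose from 0.737 ± 0.866 to 35.7 ± 9.20 TPM (log2 change 4.49 ± 0.31, SE), and TRH, the thyrotropin-releasing hormone precursor, from 9.57 ± 1.12 to 198 ± 4.92 (4.24 ± 0.15). SLC12A5, the potassium chloride exporter KCC2 that sets the response to GABA, rose from 0.798 ± 0.517 to 14.1 ± 2.00 TPM (3.10 ± 0.22). The largest decreases were those of PMEL (-3.89), a melanosome protein, PTH2 (-3.75), SPON2 (-3.49) and PENK (-3.44), the proenkephalin gene, which fell from 137 ± 17.2 to 11.7 ± 1.23 TPM.

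GABA-A receptor genes rose in 8 of 10 cases and fell in 0 (median log2 change 1.87, camera adjusted p = 1.86e-11), with GABRA2 at 3.12, GABRA5 at 2.85 and GABRA3 at 2.60. Presynaptic genes rose in 10 of 28 cases and fell in 0 (median 0.88, adjusted p = 9.76e-11), among them SYNPR (1.96), SNAP25 (1.68), which is part of the fusion machinery of vesicles, and SYN2 (1.64). Voltage-gated sodium channel genes rose in 5 of 10 cases (median 0.98, adjusted p = 1.36e-05), led by SCN2A (2.03) and SCN2B (1.43). In the cholinergic list 2 of 7 rose (median 0.92, adjusted p = 1.19e-05), including the choline transporter SLC5A7 (2.51). Neurogenic transcription factors fell in 6 of 16 cases and rose in 0 (median -0.90, adjusted p = 1.96e-11), with NEUROD1 at -1.98 and NEUROD4 at -1.86. The cell cycle list fell further in 11 of 28 cases, or 12 adjusted over the list alone (median -0.90, adjusted p = 8.81e-11), with CCNB2 and TYMS both at -1.67. For the other 5 lists the counts adjusted over the list alone were the same.

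Glutamate transport and receptor genes moved both ways, with 9 of 22 higher and 2 lower (adjusted p = 0.00179, and adjusted p = 0.116 with an estimated correlation). The metabotropic receptor GRM7 rose by 3.27 and its relative GRM2 fell by 2.69. Mitochondrially encoded genes had a median of 0.55 with 0 of 13 called by limma (adjusted p = 1.40e-05, and adjusted p = 0.348 with an estimated correlation). MAP2 (0.01), TUBB3 (-0.41), DCX (0.03) and SLC17A6 (-0.20) did not pass.

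In total 1196 genes were higher and 415 lower on day 32. The split was 943 and 560 under quantile normalization, which moved the median of all genes by -0.10, and 2697 and 166 under spike-in scaling, which moved it by 0.41, and SNAP25 lost its call at a pseudocount of 0.1 and SCN2B in FPKM.

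From day 32 to day 57 genes of hypoxia and glycolysis rose together, and the neurogenic transcription factors fell again. LDHA (ENSG00000134333.14, chromosome 11, 18394560 to 18408425), lactate dehydrogenase A, rose from 212 ± 123 to 857 ± 123 TPM (SD, n = 3, log2 change 2.14 ± 0.25, SE, adjusted p = 5.2e-05). HK2 rose from 0.972 ± 1.68 to 10.0 ± 2.71 TPM (2.78 ± 0.42), and BHLHE40, a transcription factor induced by low oxygen, by 1.89. Of that list 10 of 19 tested genes rose and 0 fell, also adjusted over the list alone (median 1.06, camera adjusted p = 1.07e-21). Other energy lists moved with it by less and with 0 genes called: nuclear-encoded oxidative phosphorylation (median 0.20, adjusted p = 1.20e-06, and adjusted p = 0.206 with an estimated correlation) and the mitochondrially encoded genes (median 0.47, adjusted p = 6.45e-08, and adjusted p = 0.259), whose mean share rose from 12.3% to 16.6% of the annotated TPM. NEUROG3 fell from 2458 ± 86.0 to 854 ± 72.8 TPM (log2 change -1.53 ± 0.16).

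The largest increases were those of LGALS1, a galectin, from 3.74 ± 0.868 to 77.2 ± 28.2 TPM (adjusted p = 2.74e-06), the small heat shock protein HSPB8 (3.61), S100B (2.93), a calcium-binding protein common in glia, and CYP2S1 (2.89). CPNE6 was listed at 0 on day 32 and reached 6.80 ± 0.999 TPM. S100B varied on day 57, at 20.8 ± 23.6 TPM. The largest decreases were those of PLA2G1B (-2.01), GPR6 (-1.90) and the histone methyltransferase EZH2 (-1.77), which went from 18.2 ± 0.590 to 5.34 ± 3.73 TPM.

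Neurogenic transcription factors fell in 4 of 16 cases and rose in 0 (median -0.74, adjusted p = 6.48e-08), with NEUROD1 at -1.23 and INSM1 at -1.16 beside NEUROG3. In the GABAergic list 2 of 7 genes rose, or 3 adjusted over the list alone, the calcium-binding protein PVALB by 2.19 and SST by 1.32 (adjusted p = 0.00455), while the median of the list was 0 and its mean 0.62. GAD1 and GAD2 were not among those 2 genes, so this call does not show a gain of GABAergic neurons. Immediate early genes, which respond to activity, rose in 3 of 12 cases, or 5 adjusted over the list alone (adjusted p = 1.88e-05, and adjusted p = 0.0717 with an estimated correlation), with NPAS4 at 2.46. Of the astrocyte list 3 of 10 rose (S100B, the aldolase ALDOC at 2.59 and SPARCL1 at 1.91, adjusted p = 0.00659, and adjusted p = 0.302 with an estimated correlation), with GFAP still below the filter. NEFH, the heavy neurofilament of large axons, rose by 2.44.

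A total of 369 genes were higher and 159 lower on day 57. The split was 438 and 101 under median-of-ratios scaling and 521 and 98 under spike-in scaling, which moved the median of all genes by 0.14. At a pseudocount of 0.1 the calls of NEUROG3, BHLHE40, INSM1 and SST were lost, and that of SPARCL1 was lost without replicate 2 or 3 of day 32.

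From day 57 to day 88 few genes changed. CPNE6 (ENSG00000100884.9, chromosome 14, 24070837 to 24078100), a calcium-dependent membrane-binding protein of neurons, rose further from 6.80 ± 0.999 to 51.9 ± 10.0 TPM (SD, n = 3, log2 change 2.75 ± 0.19, SE, adjusted p = 3.92e-07). CALCA, the precursor of calcitonin gene-related peptide, rose from 9.58 ± 1.43 to 56.2 ± 6.73 TPM (2.44 ± 0.28), and LGALS1 from 77.2 ± 28.2 to 338 ± 28.4 (2.17 ± 0.36). NPAS4, an activity-dependent transcription factor, returned from 7.68 ± 3.05 to 0.382 ± 0.0790 TPM (-2.58 ± 0.29).

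Of the named genes FAM163A (2.19) and UTS2 (2.16), the urotensin precursor, also rose, and C1QL1 (-1.68), the GABA transporter SLC6A11 (-1.51) and the glypican GPC2 (-1.32) fell. The integrated stress response list was higher as a group (median 0.42, camera adjusted p = 7.66e-08) with 0 of 17 genes called by limma and 1 adjusted over the list alone. In the sensory list 1 of 14 genes, CALCA, was higher and 1, TAC1, lower by -1.03, or 3 and 1 adjusted over the list alone (adjusted p = 0.00561, and adjusted p = 0.0674 with an estimated correlation). Glutamate transport and receptor genes had a median of -0.30 with 0 of 22 called (adjusted p = 0.00179, and adjusted p = 0.116 with an estimated correlation).

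Altogether 54 genes were higher and 19 lower, and 2010 had an unadjusted p under 0.05. Leaving out 1 library took the total of 73 to between 31, without replicate 3 of day 57, and 55, and a fit of only the compared groups called 4 higher and 0 lower. Under spike-in scaling 35 were higher and 70 lower, with the median of all genes moved by -0.20, and at a pseudocount of 0.1 the total was 19, with the calls of CPNE6 and NPAS4 kept and those of CALCA, LGALS1, FAM163A, UTS2, C1QL1, SLC6A11 and GPC2 lost. TAC1 and C1QL1 also lost theirs without single replicates, replicate 3 of day 88 among them.

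**Figure D3:**
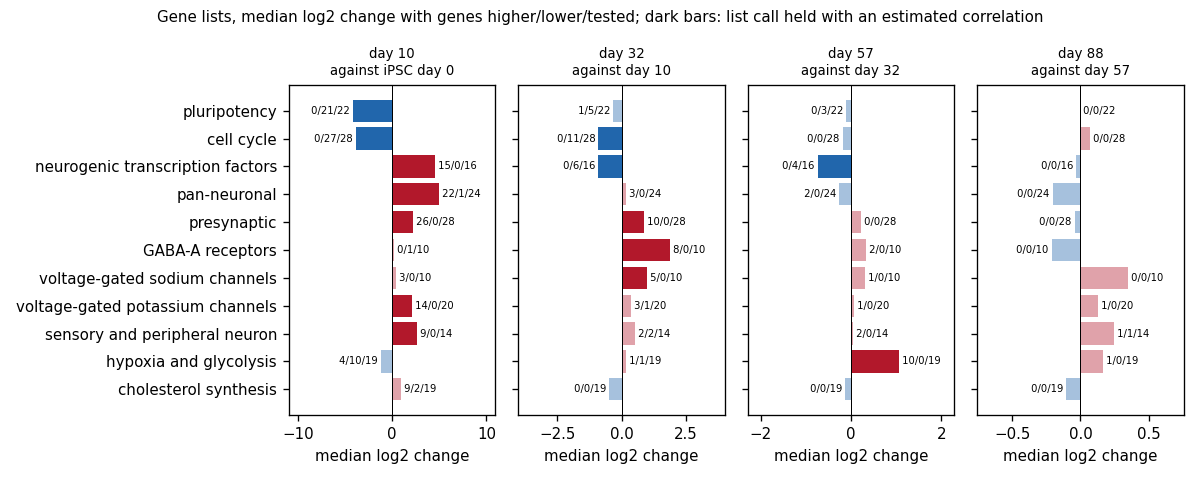
Bars give the median log2 change (x axis, own scale per panel) of 11 fixed lists (y axis) in the 4 successive comparisons, with genes higher, lower and tested beside each bar, and dark bars where the list call held with an estimated correlation. The hypoxia and glycolysis median is 1.06 on day 57 against day 32, with 10 of 19 genes higher, and the neurogenic transcription factors go from 4.53 on day 10 to -0.90 and -0.74 in the next comparisons.

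Over the whole spheroid culture, day 88 differed from day 10 by 2143 higher and 1362 lower genes. LGALS1 rose from 1.75 ± 1.63 to 338 ± 28.4 TPM (SD, n = 3, log2 change 7.18 ± 0.36, SE, adjusted p = 8.82e-11), and SNCB, beta-synuclein, from 4.36 ± 0.495 to 334 ± 60.2 (5.95 ± 0.17). MT3, a metallothionein of neurons, and CALCA were listed at 0 on day 10 and reached 73.5 ± 11.2 and 56.2 ± 6.73 TPM. The largest decreases were those of PMEL (-4.87), BTBD17 (-4.73), GRM2 (-4.70), SPON2 (-4.50) and PPP1R17 (-3.98). SNAP25 rose from 54.4 ± 7.92 to 330 ± 48.8 TPM (2.58 ± 0.21).

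Neurogenic transcription factors fell in 12 of 16 cases and rose in 0 (median -1.68, camera adjusted p = 9.76e-11), with NEUROD4 at -3.47, NEUROD1 at -3.45 and EBF2 at -3.39. Presynaptic genes rose in 15 of 28 cases and fell in 2 (median 1.05, adjusted p = 8.89e-09), with SYNPR at 2.74. Voltage-gated sodium channel genes rose in 9 of 10 cases (median 1.45, adjusted p = 1.20e-06), with SCN4B at 3.29 and SCN2B at 2.71. GABA-A receptor genes rose in 8 of 10 (median 1.55, adjusted p = 1.20e-06), with GABRA2 at 4.91. Hypoxia and glycolysis genes rose in 13 of 19 (adjusted p = 1.89e-09), with HK2 at 3.03 and LDHA at 2.85. In the cholinergic list 4 of 7 rose (adjusted p = 8.51e-04), including SLC5A7 (3.23) and the acetylcholine-synthesising enzyme CHAT (2.25). In the GABAergic list 2 of 7 rose (adjusted p = 0.00241), PVALB (5.71) and CALB2 (5.14). The GABA-synthesising enzymes GAD1 and GAD2 were not among the genes that rose, so this call does not show a gain of GABAergic neurons. Counts adjusted over the list alone were the same for these 7 lists. Cell cycle genes fell in 17 of 28 cases and rose in 1 (median -1.21, adjusted p = 5.90e-07, and adjusted p = 0.0674 with an estimated correlation). TUBB3 (-0.91), MAP2 (-0.80), DCX (-0.87) and SLC17A6 (0.20) did not pass. Under spike-in scaling 3325 genes were higher and 595 lower, and the median of all genes moved by 0.35, against -0.11 when TPM was rescaled to a sum of 1000000.

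Monolayer neurons of days 66 and 88 were compared with spheroids of days 57 and 88. CCK (ENSG00000187094.11, chromosome 3, 42257825 to 42266207), the cholecystokinin precursor, was at 2.43 and 7.70 TPM in the monolayers of days 88 and 66 against 76.9 ± 7.15 and 29.1 ± 8.85 in the spheroids of days 57 and 88 (SD, n = 3 each), a log2 change of -3.12 ± 0.33 (SE, adjusted p = 2.43e-04). SST fell by 1.20, LGALS3, a galectin, from 44.2 to 9.48 TPM, the melatonin receptor relative GPR50 by 2.39, the potassium channel subunit KCNS1 by 1.92 and EGR1, an immediate early gene, from 9.55 to 1.87 TPM. MT1E (1.41), a metallothionein, ZNF230 (1.26) and AEN (1.06), a nuclease induced by p53, were higher. In all, 6 genes were higher and 27 lower, and 1821 had an unadjusted p under 0.05. Monolayer day 66 against spheroid day 57 alone gave 11 higher and 8 lower, with 7 of the 33 calls shared, and day 88 alone gave 8 higher and 34 lower, with 12 shared.

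Neurogenic transcription factors were higher in the monolayers as a list (median 0.32, camera adjusted p = 1.19e-05) with 0 of 16 genes called by limma. Immediate early genes were lower as a list (median -0.52, adjusted p = 1.19e-05, and adjusted p = 0.0674 with an estimated correlation), with 1 of 12 called, or 2 adjusted over the list alone. The hypoxia and glycolysis list was not called (median -0.08, adjusted p = 0.188). TUBB3 (-0.29), MAP2 (-0.38), SNAP25 (-0.10) and SLC17A6 (-0.08) did not pass. With 1 library per monolayer day the spread of monolayers is unknown, and the calls of CCK, SST, LGALS3, GPR50, KCNS1, MT1E and ZNF230 were lost at a pseudocount of 0.1 and those of AEN and EGR1 without replicate 3 of day 57. Under spike-in scaling 11 genes were higher and 20 lower, and the median of all genes moved by 0.12.

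The lots of undifferentiated cells were compared with each other because both served as day 0. Lot 2 differed from lot 1 by 268 higher and 1156 lower genes, and by 671 and 1202 without replicate 3 of lot 1. HIST1H1E (ENSG00000168298.6, chromosome 6, 26156354 to 26157107), a linker histone, was at 35.2 ± 7.21 TPM in lot 1 and 3.54 ± 0.648 in lot 2 (SD, n = 3 each, log2 change -2.98 ± 0.27, SE, adjusted p = 7.24e-07). The linker histones HIST1H1D (-2.97) and HIST1H1B (-2.88) were also lower, as were ARHGDIA (-2.92) and MTRNR2L12 (-2.85). Histone genes of 1 cluster resemble each other and MTRNR2L12 resembles a mitochondrial RNA, so how their reads were split between copies is uncertain. Whether the lower histone levels come from the cells or from how the libraries were made was not tested.

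Higher in lot 2 were WLS (2.15 ± 0.28), which carries WNT proteins to the cell surface, at 7.31 ± 1.20 against 0.884 ± 0.366 TPM, FLRT3 (1.92) and BNIP3 (1.88). Of the cholesterol synthesis list 7 of 19 genes were lower and 0 higher, also adjusted over the list alone (median -0.38, camera adjusted p = 1.52e-04, and adjusted p = 0.142 with an estimated correlation). They included MVD (-2.07 ± 0.16), an enzyme of the mevalonate pathway, and LSS (-1.92 ± 0.15), the lanosterol synthase. POU5F1 (0.07 ± 0.35), NANOG (-0.12 ± 0.19) and SOX2 (-0.24 ± 0.27) did not pass. Spike-in references summed to 358 to 551 TPM in lot 1 and 2303 to 3126 TPM in lot 2. Scaling by them left 1 gene higher and 13180 lower and moved the median of all genes by -1.58, and median-of-ratios scaling gave 470 higher and 1038 lower.

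Transcript pairs whose balance shifts as neurons mature were described by the difference of their log2 values. The exporter SLC12A5 minus the importer SLC12A2 of chloride went from -1.60 ± 0.38 on day 10 to 1.56 ± 0.22 on day 32, 2.17 ± 0.49 on day 57 and 1.64 ± 0.18 on day 88 (SD, n = 3 each), and was 0.98 and 0.74 in the monolayers of days 66 and 88. GRIN2A minus GRIN2B of the NMDA receptor was 0.49 ± 0.29 on day 10 and 0.65 ± 0.36 on day 88, a shift smaller than the spread between replicates, and GRIN2B was listed at 0 on day 10. At a pseudocount of 0.1 the shift was -1.01.

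**Figure D4:**
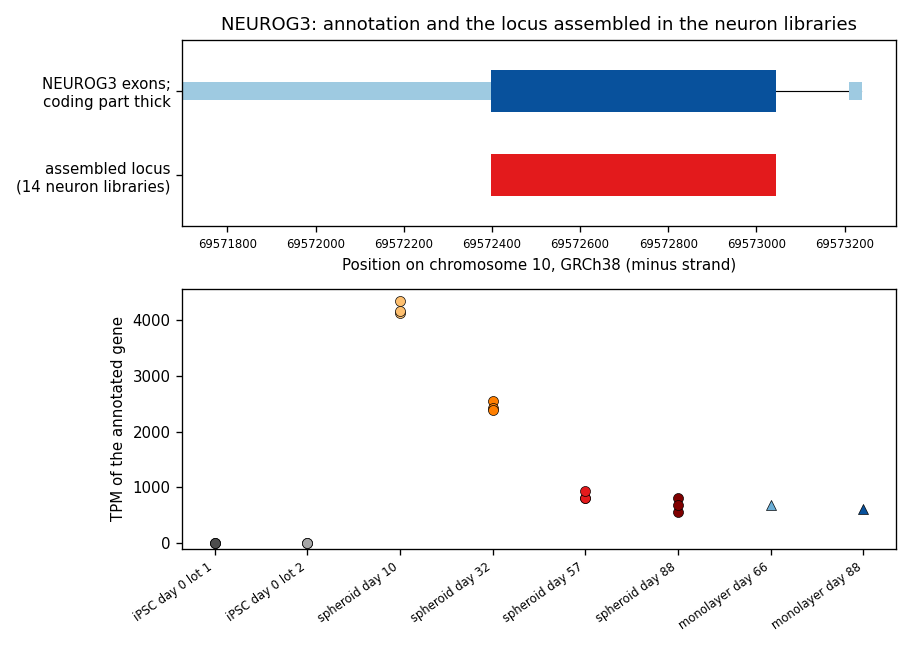
Upper panel, the annotated exons of NEUROG3 with the coding part thick and the locus assembled in the 14 neuron libraries, by position on chromosome 10 (GRCh38, x axis). Lower panel, TPM of the annotated gene (y axis, linear) in each library by group (x axis), at most 0.660 in iPSC and 559 to 4346 in the neurons.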

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

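The tests of the source of the NEUROG3 signal were chosen after the result was seen, as were those of dividing cells and of the spheroid form of culture, while those of normalization, gene length and splits were set before their values but after counts of calls under the alternatives had been seen.

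Outside the main measurement, a locus over the NEUROG3 coding sequence was assembled in 14 of 14 neuron libraries and in 0 iPSC libraries, at 1193.5 TPM in the lowest neuron library, and its limits lay within a base of the coding limits at 69572399 and 69573043 on chromosome 10. The coding part is 645 of 1376 exonic bases, so whole NEUROG3 mRNA as the source would place 53.1% of the bases outside it. At most 0.0% lay outside and at least 100% inside, which argues against endogenous whole mRNA. The locus was picked by its limits, so these shares largely restate them. The main exon ends at 69573044, next to the upper coding limit, so mainly the lower limit tells the sources apart, where that exon runs on to 69571698. Reads shared with the paralogs NEUROG1 and NEUROG2 are also argued against, since these summed to at most 0.145% of the NEUROG3 TPM. Among 14020 coding genes 1, NEUROG3, had a locus matching its coding limits within 10 bases in all neuron and no iPSC libraries, while RPS2, a ribosomal protein gene, had one in 11 neuron and 0 iPSC libraries, so such a match is not unique to NEUROG3. An introduced NEUROG3 coding sequence is consistent with these values as a hypothesis, since the introduced factors are not given in the sources used here.

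Spike-in references reached 2302.5 TPM or more in every library of lot 2 and at most 550.7 in lot 1. Lot 2 also had more lower than higher genes. Quantile normalization left the higher share of calls at 27.83% (18.8% as reported and 35.8% without replicate 3 of lot 1), so TPM scaling does not account for the excess alone. Genes called lower were shorter, with a median of 2723 exonic bases against 3713 for genes not called and 3625 for higher genes. The trend with length was taken off as the median change in 50 bins of length, from -0.399 to 0.123. Without it 89.95% of the genes called lower kept a log2 change of -1 or below. A shift shared by all genes of like length thus does not account for the lower calls alone, while a length effect on part of the genes stays open. A lower share of dividing cells is argued against by the cell cycle list, whose median was 0.36. By contrast 13 of 50 histone cluster genes were lower and 0 higher. Whether their levels follow cell division or the making of the libraries here was not tested. A difference between the lots themselves stays open as untested, and it cannot be told apart from a difference in RNA amount, handling or library batch, since the libraries of each lot carry names of their own series.

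The rise of the hypoxia and glycolysis list from day 32 to day 57 was weighed against normalization and culture form. Under quantile normalization its median was 1.099, which argues against normalization as the whole cause. The spheroid form would place monolayers well below spheroids, but the mean difference was -0.193 ± 0.09 (SE over 19 genes), -0.341 ± 0.084 on day 88 alone, and monolayer day 66 was 1.13 above spheroid day 32. The mean rise from day 32 to day 57 was 1.18 ± 0.151, so the list in these monolayer libraries lay below the spheroids by less than that rise. These errors measure the spread between genes and not between cultures, and each monolayer day is 1 library. Whether the spheroid form had a part therefore stays open. A change with time in culture is consistent with these values as a hypothesis and was not tested.

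Ribosomal DNA loci held at least 8.08% of the signal in each neuron library and at most 5.22% in an iPSC library.

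For day 10 against day 0, 1 of 84 splits, the real one, gave as many calls (8279 with day 0 as 1 group, highest other 1901), which argues against an arbitrary division of these libraries. The splits treat all libraries as exchangeable, although the iPSC came from 2 lots. They cannot tell cell type apart from naming series, depth or culture form. The other comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. Their real and highest other counts were 1611 and 4 for day 32, 528 and 4 for day 57, 73 and 3 for day 88 against day 57, 3505 and 2 for day 88 against day 10, and 1424 and 99 for the lots. Every other split mixes the groups compared, here and for day 10, so a real difference between them widens the spread and lowers the count. The highest other counts are therefore not a level of false calls, and the size of the gap adds no support.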

How the results depend on the processing

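The rescaling to a sum of 1000000 and the assembled-locus TPM were tests chosen after the data were seen. Counts of called genes stayed within 1.5 times for day 10 against day 0 (6519 to 10226, without each replicate 8268 to 8407) and for day 88 against day 10 (without each replicate 3407 to 3619). A like count does not mean the same genes. With assembled-locus TPM 6373 of the 8316 calls of day 10 against day 0 were shared, 6331 of them in the same direction. Shared calls were 1883 of 3505 for day 88 against day 10 and 655 of 1424 for the lots. They were 627 of 1611 for day 32 against day 10, 146 of 528 for day 57 against day 32 and 11 of 73 for day 88 against day 57. For day 32 against day 10 (1611) spike-in scaling gave 2863 and assembled loci 1031 (without each replicate 1452 to 1608). For day 57 against day 32 (528) FPKM gave 350 and assembled loci 294 (416 to 496). For day 88 against day 57 (73) a pseudocount of 0.1 gave 19, assembled loci 46 and a fit of only the compared groups 4, and leaving out 1 library gave 31 to 55: 36 and 31 without replicates 2 and 3 of day 57, and 47, 43 and 41 without replicates 1, 2 and 3 of day 88. For the monolayers (33) a pseudocount of 0.1 gave 16, no filter 66, quantile normalization 51, assembled loci 99, only the compared groups 8 and day 66 against spheroid day 57 alone 19 (25 to 41 without each spheroid replicate). For the lots (1424) spike-in scaling gave 13181 (1249 to 1873). The fits of only the compared groups hold fewer libraries and take the spread from these groups alone, while the main fit pools it with the iPSC. Which of these lowered the counts, and the cause of the other changes, was not tested. Of 89 list calls 26 held with an estimated correlation and 22 were lost in at least 1 other setting. Of 448 called results for named genes 344 were called in every setting tried for them, 104 were lost in at least 1 and 0 turned. Named genes were not tried in the fit of only the compared groups or in limma without trend or robust settings. Rescaled TPM, assembled loci, and single lots or monolayer days were not tried for them either, so these counts do not cover the settings that cut the calls most. Spike-in scaling was looked at apart, and there 0 called genes outside the lot comparison turned. In the lot comparison it moved the median of all genes by -1.58, so turns there say nothing about single genes. List medians that changed sign under it included cholesterol synthesis on day 32 (-0.48 to 0.02) and hypoxia on day 88 against day 57 (0.16 to -0.06), beside moves of the median of all genes by 0.41 and -0.20. SLC12A5 minus SLC12A2 from day 10 to day 88 (3.24, 3.07 to 3.44 without each replicate) was 4.35 at a pseudocount of 0.1 and 2.64 in FPKM. GRIN2A minus GRIN2B (0.16, 0.01 to 0.37) was -1.01 at a pseudocount of 0.1, where values near 0 weigh most. With the replicate number as a block the counts were 8320, 1608, 515, 63, 3506, 29 and 1420 in the order of the report, and 88 lists were called. The numbers do not pair the libraries, since 1 of 45 same-numbered pairs had a correlation of deviations above 0.1 and 8 of 18 libraries correlated best with their own number. Depth limits genes of low level most in the neurons, at 378 to 655 aligned megabases.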

Other observations

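The genes of the next paragraphs were chosen after their values were seen, and no explanation was tested.

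Neuropeptide genes followed different courses in the spheroids. TAC1 was at 237 ± 30.6, 343 ± 44.8, 356 ± 25.6 and 177 ± 48.0 TPM on days 10, 32, 57 and 88 (SD, n = 3 each), and SST at 268 ± 45.7, 172 ± 19.0, 431 ± 21.9 and 361 ± 44.2. TRH peaked at 307 ± 14.8 TPM on day 57, and CCK, the cholecystokinin precursor, at 76.9 ± 7.15, each with a lower mean on day 88 (167 ± 38.7 and 29.1 ± 8.85). GAL, the galanin precursor, reached 143.5 ± 219 TPM on day 88 against 10.4 ± 3.13 on day 57, CARTPT 65.6 ± 103 and PENK 35.8 ± 53.5 on day 88, each with an SD above the mean, so these 3 means rest on uneven libraries.

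Among transcription factors, LHX9 rose by 5.46 and ONECUT1 by 5.41 on day 10. LHX9 fell by 1.03 from day 10 to day 32, where ONECUT1 did not pass (0.30), and from day 10 to day 88 they fell by 2.73 and 1.06. HOXD1 was listed at 0 on day 10 and reached 3.77 ± 0.769, 11.5 ± 3.26 and 32.4 ± 11.9 TPM on days 32, 57 and 88, with 76.9 TPM in the monolayer of day 88 and 6.41 TPM in that of day 66. POU4F1, a sensory neuron factor, rose by 3.00 on day 10. On the second principal component the monolayer of day 66 lay at -12.2, between the spheroids of day 32 and day 57, and that of day 88 at -41.9, within the range of the spheroids of day 88.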
